A study of Bos taurus with 6 samples.

How the data were processed

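Poly(A) RNA libraries of bovine endometrial side population (SP) and main population (MP) cells, 3 each, were compared. Per the labels' protocols, cells were sorted by Hoechst fluorescence with propidium iodide to exclude dead cells, RNA was extracted with a micro column kit, and libraries were made with a stranded mRNA kit and converted for MGI sequencing. No antibody gate is given in the labels. The labels give the same kits for both populations, while, per the file headers, the columns of MP alone carry the word micro, whose meaning is not given. Per the submitters' processing notes, cutadapt 2.5 and HISAT2 2.1.0 and the genome build ARS-UCD1.2 were used. The tool that computed the values, the annotation version and whether strand was used in counting are not given in the sources used here.

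The deposited values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library) for each library, per the file headers, with no scaling between libraries stated. FPKM depends on the other transcripts of a library, so a few abundant genes shift all others, and the sums of FPKM ranged from 647501 to 963629. Mitochondrially encoded genes took 9.9% to 16.4% of this sum in SP and 10.5% to 23.4% in MP. These shares are not alike in content: the sums of MP lack COX1, COX3, ATP6 and ATP8, which are listed at 0 there. All 9 mitochondrially encoded genes with a value in every library were lower in SP (median log2 fold change −1.29), a difference that the overlapping shares hide. Each file lists 34733 named genes and 1 row without a gene name, which pools 662 symbols and held 0.18% to 0.35% of the values in SP and 0.74% to 1.91% in MP; this row was left out of sums and tests. Of the named entries 1690 repeat a symbol already listed, and each was kept as its own gene. An exact 0 can be a failed estimate, since COX1, a gene that every cell uses, is listed at 0 in 3 libraries. Such genes are described as listed at 0.

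Counts were not in the files. The depth of each library was estimated from the lowest values in genes of 600 to 4000 bp locus length, as the value that 1 fragment takes. The estimate was tested on simulated data. Relative depth from the ratio of low values between libraries gave 1.60 and 1.82 for SP replicates 2 and 3 and 2.32, 3.18 and 1.99 for MP replicates 1 to 3, relative to SP replicate 1. The lower depth of SP limits statements on genes near 0 in SP.

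Groups and replicate numbers came from the sample titles. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 12127 in all, on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Within this text rose, fell and called refer to this test. For a single gene the exact two-sided permutation test of 3 against 3 libraries cannot go below p = 0.1. Before the data were examined 27 gene lists, the rule for named genes, the tests and most alternatives were fixed. Lists with at least 4 tested members, 25 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists. With an estimated correlation none of the 25 lists passed (lowest adjusted p = 0.136; 2 at an unadjusted p under 0.05). With fry, which asks whether the genes of a list move on balance one way and compares them with no other gene, 8 passed.

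The named genes were ABCG2, ABCB1 and ABCC1; the 10 genes with the largest fold change in each direction among called genes with a symbol whose SP and MP values did not overlap; and for each list up to 4 called members by smallest p, or, where none was called, the 2 with the highest mean FPKM. This gave 111 genes. The loci of 16 overlap that of another tested gene, among them ABCG2 with LOC781421, ACTA2 with FAS, AIF1 with NCR3, TIMP1 with ARAF, TPI1 with USP5 and NDUFA1 with NKAP, and reads of such pairs may not be told apart. Symbols of 95.8% of the tested genes were found in the gene table of assembly ARS-UCD2.0, which was used for names, gene classes and the lengths of mitochondrial genes; 2 list members, TPSB1 and MMP23B, were matched to TPSB2 and MMP23 through it, and 8 list members had no match. Coordinates are those of the files, counted from 1, and cover the locus from its first to its last base, introns included. A listed locus can be wider than the gene and shared by several, as ATP6, ATP8 and COX3 are all listed at 8129 to 9750.

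The limma fit was tested on simulated data for the SP against MP comparison with 12127 genes, of which 200 were changed. It called 14% of genes changed by 1 on the log2 scale, 88% of those changed by 2 and 100% of those changed by 3 or 4 in the right direction, and 5.62% of its calls were unchanged genes. With no change it called 0 lists. The simulated genes varied independently, so this cannot show false list calls that arise from correlated genes. Fewer genes were changed in the simulation than the 4759 called in the data, so the shares found may not carry over. Alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 FPKM, median-of-ratios, quantile and total (TPM) scaling, eBayes without a trend and robust, array weights, the replicate number as a block, leaving out each library and each replicate number, and leaving out mitochondrially encoded and ribosomal protein genes. Added after seeing the data were list members matched by exact symbol only, a fit without the 255 tested genes listed at 0 in a library and a correction of each library for its trend along genomic span. No 2 libraries held the same values (highest r = 0.967).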

Results

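RNA was measured in side population (SP) and main population (MP) cells of cow (Bos taurus) endometrium, the lining of the uterus, in the luteal phase of the estrous cycle. Per the labels' protocols, uteri came from slaughterhouses, intercaruncular endometrium without its luminal epithelium was digested with collagenase, and the stromal cell preparation was stained with the DNA dye Hoechst. SP cells pump the dye out through ABC transporters, a property long used to enrich stem-like cells, and verapamil, which blocks such transporters, marks the gate. MP cells retain the dye. The series holds 6 libraries, 3 of SP and 3 of MP. The files give FPKM and no counts. The steps of the low values put the depth, in units of 1e+06 fragments, at about 12.7, 20.7 and 22.9 in SP replicates 1 to 3 and at 29.2, 39.9 and 24.6 in MP replicates 1 to 3, so every SP library was shallower than every MP library. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical in part. Values of some MHC class II genes, given at the end, argue against a single animal behind all replicates. Per the file headers, the columns of all MP libraries carry the word micro and those of the SP libraries do not. Its meaning is not given, and a difference in handling that it marked would not be separable from the population.

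The first question was whether the sorted cells carried the transporters on which the gate rests. ABCB1, which encodes P-glycoprotein (chromosome 4, 32879459 to 32982658, build ARS-UCD1.2), was at 81.2 ± 28.7 FPKM in SP and 8.37 ± 7.35 FPKM in MP (SD, n = 3 each), a log2 fold change of 3.34 ± 0.52 (SE; limma adjusted p = 0.0042). Its 3 SP values, 111, 54.1 and 78.3 FPKM, all lay above the MP values of 3.76, 4.50 and 16.8 FPKM. ABCG2 (chromosome 6, 36475491 to 36603215), the other main exporter of the dye, was at 138, 97.9 and 66.1 FPKM in SP replicates 1 to 3 and at 17.1, 23.7 and 71.8 FPKM in MP replicates 1 to 3. Its log2 fold change was 1.61 ± 0.52 (SE) with a limma adjusted p of 0.0432, but MP replicate 3 lay above SP replicate 3, and the exact two-sided permutation test of 3 against 3 libraries gave p = 0.2, where 0.1 is the smallest p it allows. ABCC1 did not pass, at 5.32 ± 1.94 FPKM in SP and 2.61 ± 0.43 FPKM in MP (SD, n = 3 each; limma adjusted p = 0.0588), but passed in 2 of 22 alternatives (adjusted p from 0.0479 to 0.267). Among the 12 ABC transporters tested, ABCB1, ABCG1, ABCB4 and ABCG2 rose, 8 did not pass and none fell; adjusted over the list alone, 6 rose. ABCB4 was under 1 FPKM in every MP library, so the filter on low values fixed its direction in advance. Endothelial markers, described below, rose in the same libraries, and their median was likewise highest in MP replicate 3 among the MP libraries (7.34, 14.6 and 51.1 FPKM). ABCG1, a cholesterol exporter, rose by 2.64 ± 0.67 and ABCB4 by 1.79 ± 0.31 on the log2 scale (SE; limma adjusted p = 0.019 and 0.00576), with ABCG1 called in 16 of 23 alternatives (adjusted p from 0.00243 to 0.138). The list as a whole did not pass (camera adjusted p = 0.0887), but passed in 3 of 26 alternatives, with quantile normalization (0.0466), without MP replicate 3 (0.0285) and without replicate number 3 (0.0471), over a range of adjusted p from 0.0285 to 0.635. The call of ABCG2 was lost without any one of SP replicates 1, 2 and 3 or MP replicates 1 and 2 (limma adjusted p from 0.0553 to 0.131), whereas without MP replicate 3 it held with a log2 fold change of 2.21 (limma adjusted p = 0.00572). It was also lost with no filter on low values (limma adjusted p = 0.0948), without mitochondrially encoded and ribosomal protein genes (0.0787) and after a correction for genomic span chosen after seeing the data (0.0673). The same held with the replicate number as a block (limma adjusted p = 0.0679) and without replicate numbers 1 and 2 (0.274 and 0.219). ABCG2 was called in 12 of 23 alternatives, over a range of adjusted p from 0.00572 to 0.274.

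The second question was how the transcriptomes of the populations differed. The first principal component held 71.5% of the variance over the tested genes and parted the SP from the MP libraries. Pairs within SP had Pearson r from 0.950 to 0.967 across genes, pairs within MP from 0.925 to 0.937, and pairs between the populations from 0.736 to 0.880. MP replicate 3 lay nearest to SP, with r from 0.832 to 0.880, against 0.736 to 0.789 for MP replicate 1.

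**Figure D1:**
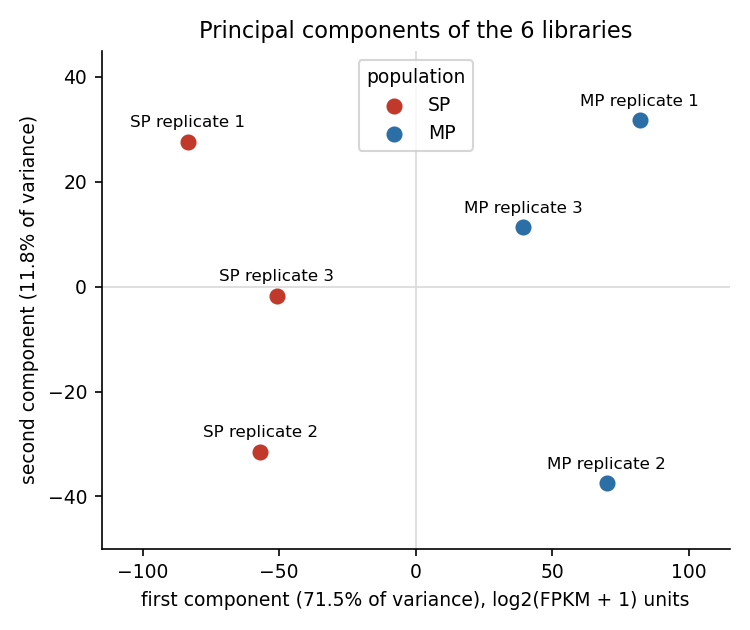
Principal components of log2(FPKM + 1) over the 12127 tested genes, with the first component (71.5% of the variance) on the x axis and the second (11.8%) on the y axis; each point is a library, red for SP and blue for MP. The 3 SP libraries lie on the left and the 3 MP libraries on the right, with MP replicate 3 nearest to SP.

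Of 12127 genes tested, 4759 differed between SP and MP (limma, Benjamini-Hochberg adjusted p under 0.05), 2490 higher and 2269 lower in SP. In 4715 of the 4759 the 3 SP values all lay on one side of the 3 MP values. Over all tested genes this held for 54.8%, against the 10% that chance gives for 3 against 3. The filter raises this share, since a gene under 1 FPKM in every library of a population is tested only if its values lie apart. The direction of such a gene is fixed in advance. Among the named genes these were ABCB4, OAS2, CCNE2 and the mitochondrially encoded genes listed at 0, all low in MP. Low in SP were DPT, WNT2, ADAMTS5, HAND2, FGF10, TNF, BOLA-DOA and ALDH1A3. The same held for CD79A, MZB1, FCER1A, HPGDS and the leukocyte markers named below for this reason. A change of at least 2-fold was seen in 3511 of the called genes. The direction of the split depends on the scaling. With FPKM rescaled to a sum of 1e+06 per library (median of all genes shifted to 0.19) 68% of the calls were higher in SP, and without mitochondrially encoded and ribosomal protein genes (median −0.15) 37.8%, against 52.3% as deposited. The number of calls fell to 2481, 3137 and 3147 without SP replicates 1, 2 and 3, to 2601 and 2421 without MP replicates 1 and 2, and to 4455 without MP replicate 3.

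The genes most raised in SP by the fixed rule began with COX1, ATP8, COX3 and ATP6, mitochondrially encoded subunits of the respiratory chain and ATP synthase. They are listed at 0 in all 3 MP libraries, and no fold is given. COX1 (mitochondrial genome, 5687 to 7299) was at 15515, 9627 and 17922 FPKM in SP replicates 1 to 3, COX3 at 14586, 9509 and 13640 FPKM, ATP8 at 13069, 9543 and 20453 FPKM and ATP6 at 7687, 6171 and 10093 FPKM. The 9 other mitochondrially encoded genes were all lower in SP (median log2 fold change −1.29, 7 passing). Next came CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor (chromosome 21, 33949125 to 33955228), at 577 ± 348 FPKM in SP and 70.4 ± 57.9 FPKM in MP (SD, n = 3 each; log2 fold change 3.52 ± 0.92 SE, limma adjusted p = 0.0213; called in 20 of 23 alternatives, adjusted p from 0.0112 to 0.1). TNFRSF11B, which encodes osteoprotegerin (chromosome 14, 45105393 to 45624890), rose by 3.47 ± 0.49 (SE) on the log2 scale, from 8.34 to 87.1 FPKM. ABCB1, TNFRSF10D, NLRC5 and GNAT1 completed the 10, with log2 fold changes from 3.24 to 3.34.

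The genes most reduced in SP were largely transcripts of mast cells, macrophages and lymphocytes. PTI, the pancreatic trypsin inhibitor gene (chromosome 13, 74296024 to 74300843), was at 9.47 ± 11.3 FPKM in SP and 1409.8 ± 419.9 FPKM in MP (SD, n = 3 each), a log2 fold change of −7.58 ± 0.68 (SE; limma adjusted p = 0.000816). The mast cell genes TPSB2 (a tryptase) and CPA3 (carboxypeptidase A3) had log2 fold changes of −7.39 and −5.55. The complement genes C1QA, C1QC and C1QB, expressed by macrophages, had −6.53, −5.91 and −5.59, and the lymphocyte protease GZMB and the chemokine CCL4 −6.18 and −6.13. GZMB is listed at 0 in SP replicate 1. The rest of the 10 were BRB, a ribonuclease (−6.20), and PENK, the enkephalin precursor (−5.91). PTI, TPSB2, BRB and GZMB belong to families with similar copies, so their split of reads is uncertain.

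Markers of endothelial cells, which line blood vessels, rose in SP. Of 19 tested, 17 rose, none fell and CLDN5 and LYVE1 did not pass; adjusted over the list alone 17 rose. The median log2 fold change was 2.29 (camera adjusted p = 1.18e-05; adjusted p = 0.635 with an estimated correlation). With fry the list did not pass (adjusted p = 0.0728). CDH5, the adhesion molecule VE-cadherin, was at 148 ± 25.7 FPKM in SP and 25.5 ± 22.9 FPKM in MP, EMCN (endomucin) at 469 ± 146 and 101 ± 81.7 FPKM, and TEK, the angiopoietin receptor, at 26.0 ± 6.95 and 5.71 ± 4.97 FPKM (SD, n = 3 each). Their log2 fold changes were 2.88 ± 0.61, 2.46 ± 0.52 and 2.23 ± 0.50 (SE; limma adjusted p = 0.0103, 0.0108 and 0.0127). SHANK3 rose by 2.30 ± 0.33. The median endothelial marker stood at 126, 78.3 and 91.6 FPKM in SP replicates 1 to 3, and at 7.34, 14.6 and 51.1 FPKM in MP replicates 1 to 3, so MP replicate 3 lay between the other MP libraries and SP.

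Markers of the stromal fibroblast, the main cell of the endometrial stroma, fell in SP. Of 22 tested, 17 fell and none rose; adjusted over the list alone 18 fell. The median log2 fold change was −3.20 (camera adjusted p = 3.2e-08; adjusted p = 0.468 with an estimated correlation). DCN (decorin) was at 154 ± 35.8 FPKM in SP and 3884 ± 2283 FPKM in MP (SD, n = 3 each; log2 fold change −4.48 ± 0.47 SE, limma adjusted p = 0.00133). PDGFRA, a receptor of fibroblasts, was at 0.885 ± 0.588 and 16.8 ± 8.01 FPKM, FBLN1 (fibulin 1) at 17.0 ± 9.52 and 427 ± 305 FPKM and DPT (dermatopontin) at 0.317 ± 0.144 and 11.7 ± 4.08 FPKM. Pericyte and smooth muscle markers fell in 11 of 15, with 12 adjusted over the list alone, none rose, and the median was −1.76 (camera adjusted p = 1.67e-05; adjusted p = 0.468 with an estimated correlation). Among them the contractile genes ACTA2, DES, CNN1 and LMOD1 had log2 fold changes of −2.49, −2.76, −2.92 and −1.47.

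The tested markers of leukocytes fell together with the fibroblast markers. A marker under 1 FPKM in every SP library was tested only if all 3 MP values reached 1 FPKM. The filter then fixed its direction in advance, as for CD3E, CD4, NKG7, CD8B and AIF1. Tested were 14 of 19 listed myeloid, 9 of 20 T and NK cell, 6 of 8 mast cell and 3 of 12 B cell and plasma cell markers. Of 14 myeloid markers 12 fell and none rose, 12 also adjusted over the list alone, with a median log2 fold change of −3.31 (camera adjusted p = 1.32e-08; adjusted p = 0.136 with an estimated correlation). Without replicate number 3 the list did not pass (camera adjusted p = 0.086). The filter then also left out C1QA, C1QC, TYROBP and AIF1, which were under 1 FPKM in both remaining SP libraries. TYROBP, a signalling adaptor of myeloid cells, was at 0.620 ± 0.640 FPKM in SP and 75.2 ± 32.6 FPKM in MP (SD, n = 3 each), and AIF1, listed at 0 in SP replicate 1, at 30.2 to 51.4 FPKM in MP. Of 9 T and NK cell markers 8 fell and CCL5 did not pass over all genes (limma adjusted p = 0.0786), while adjusted over the list alone 8 fell and 1, CCL5, rose (median −2.17, camera adjusted p = 7.84e-05; adjusted p = 0.468 with an estimated correlation). At a mean of at least 5 FPKM the list did not pass (camera adjusted p = 0.0598). CD3E, NKG7 and CD4 had log2 fold changes of −3.57, −3.62 and −2.21. CD8B is listed at 0 in the 3 SP libraries and was at 2.99, 2.87 and 4.93 FPKM in MP. Of 6 mast cell markers 4 fell, with 4 adjusted over the list alone, and none rose (median −3.58, camera adjusted p = 0.013; adjusted p = 0.468 with an estimated correlation), among them FCER1A (−4.03) and HPGDS (−3.13). With members matched by exact symbol only, an alternative chosen after seeing the data that leaves out TPSB2, it did not pass (camera adjusted p = 0.0641). The list passed in 17 of its 25 alternatives (adjusted p from 0.00153 to 0.468) and was lost without MP replicates 1, 2 or 3 (camera adjusted p = 0.165, 0.1 and 0.291), without replicate numbers 1 or 2 (0.142 and 0.223) and at a mean of at least 5 FPKM (0.0723). In the fits without an MP library or a replicate number, the filter also left out FCER1A and HPGDS. Both were under 1 FPKM in every SP library. The losses in these fits thus came with a changed membership of the list. Of 3 B cell and plasma cell markers, too few for the list test, CD79A and MZB1 fell (−1.58 and −2.03; MZB1 called in 9 of 16 alternatives, adjusted p from 0.023 to 0.119), and 3 fell adjusted over the list alone. The only erythroid marker tested, HBQ1, was at 1.12 ± 0.184 FPKM in SP and 1.58 ± 0.678 FPKM in MP (SD, n = 3 each) and did not pass.

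Epithelial markers were present in both populations. None of 16 passed over all genes or adjusted over the list alone, with a median log2 fold change of −0.57 (camera adjusted p = 0.265). The list passed, downward, in 2 of 26 alternatives, without SP replicate 2 and without replicate number 3, over a range of adjusted p from 0.0226 to 0.902. EPCAM stood at 30.3, 432 and 134 FPKM in SP replicates 1 to 3 and at 76.9, 609 and 56.6 FPKM in MP replicates 1 to 3, a log2 fold change of −0.19 with a 95% interval from −2.78 to 2.39. CLDN4 was at 372 ± 306 FPKM in SP and 1246 ± 1108 FPKM in MP (SD, n = 3 each; limma adjusted p = 0.122). It was called lower in 1 of 23 alternatives (limma adjusted p from 0.0216 to 0.327).

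**Figure D2:**
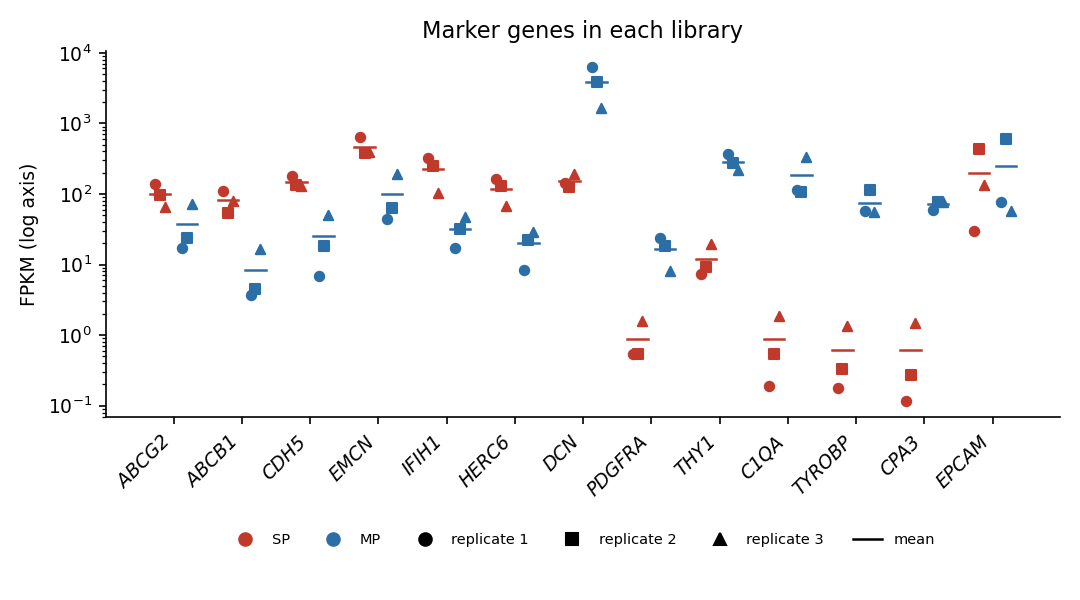
FPKM on a log axis for 13 genes of the text (x axis), with red points for SP, blue points for MP, a symbol for each replicate number and a bar at each group mean. The SP values of ABCB1, CDH5, EMCN, IFIH1 and HERC6 lie above all MP values, those of DCN, PDGFRA, THY1, C1QA, TYROBP and CPA3 lie below, and those of ABCG2 and EPCAM overlap with MP.

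Interferon stimulated genes rose in SP. Of 22 tested, 17 rose and none fell; adjusted over the list alone 19 rose. The median log2 fold change was 2.07 (camera adjusted p = 5.78e-06; adjusted p = 0.635 with an estimated correlation). With fry it did not pass (adjusted p = 0.0548). IFIH1, a cytoplasmic sensor of double-stranded RNA, was at 225 ± 112 FPKM in SP and 31.7 ± 14.9 FPKM in MP (SD, n = 3 each; log2 fold change 2.75 ± 0.50 SE, limma adjusted p = 0.0065). HERC6, DDX58 (the RNA sensor RIG-I) and OAS2 had log2 fold changes of 2.58, 1.75 and 2.36. The median member was at 110.5, 93.6 and 41.2 FPKM in SP replicates 1 to 3 and at 11.2, 20.5 and 23.1 FPKM in MP replicates 1 to 3. OAS2 and the OAS1 genes have similar copies, and the locus of OAS2 overlaps that of OAS1Y. Endothelial markers rose in the same libraries (median 2.29, 17 of 19).

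Of 17 genes of Notch signalling, 10 rose and 2 fell, the same counts adjusted over the list alone (median log2 fold change 1.11, camera adjusted p = 0.0355; adjusted p = 0.635 with an estimated correlation). The target gene HES4 rose by 2.98 ± 0.50, NOTCH1 by 2.00 ± 0.37 and NOTCH4, a receptor of endothelial cells, by 2.08 ± 0.44 (SE), while NOTCH2 had a log2 fold change of −2.17. SP replicate 1 stood apart: the median member was at 20.3, 7.28 and 6.94 FPKM in SP replicates 1 to 3 and at 4.63, 5.31 and 5.29 FPKM in MP replicates 1 to 3, HES4 at 63.4, 26.6 and 14.4 FPKM and NOTCH1 at 17.1, 6.14 and 6.92 FPKM in SP. Without replicate number 1 the median log2 fold change was 0.69. The list was lost without MP replicate 1 (camera adjusted p = 0.162), without MP replicate 3 (0.07), without replicate number 1 (0.142), with array weights (0.063) and with fry (0.0728), over a range of adjusted p from 0.00792 to 0.635. Endothelial markers rose in the same libraries.

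Nuclear genes of oxidative phosphorylation fell in SP. Of 26 tested, 15 fell and none rose; adjusted over the list alone 18 fell. The median log2 fold change was −0.83 (camera adjusted p = 1.58e-05; adjusted p = 0.136 with an estimated correlation). The respiratory chain genes NDUFA1, NDUFA2, NDUFA4 and NDUFB3 had log2 fold changes of −1.85 ± 0.23, −1.42 ± 0.22, −1.68 ± 0.26 and −1.94 ± 0.34 (SE). Of 80 ribosomal protein genes, 75 had a log2 fold change under 0 and 13 were called lower, against 2269 of 12127 over all genes. Of 16 snRNA genes, 15 lay under 0 and 6 were called lower, with a median of −1.95. The median of the ribosomal protein genes was −0.50, and it was −0.55, −0.29 and −0.28 under median-of-ratios, quantile and total scaling. Fold changes also followed the genomic span of the locus listed for each gene, with Spearman rho = 0.217 across genes, which are not independent replicates. Between libraries of the same population rho lay between −0.0541 and 0.0296. In the same libraries endothelial markers rose (median 2.29) and fibroblast and myeloid markers fell (medians −3.20 and −3.31).

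In the prostaglandin pathway 1 of 15 genes rose and 4 fell, the same counts adjusted over the list alone (median log2 fold change −0.88, camera adjusted p = 0.0385; adjusted p = 0.493 with an estimated correlation). The cyclooxygenases PTGS1 and PTGS2 were at 1.65 ± 0.616 and 4.26 ± 3.00 FPKM in SP and at 12.6 ± 2.66 and 14.3 ± 3.45 FPKM in MP (SD, n = 3 each; limma adjusted p = 0.00193 and 0.0174; PTGS2 called in 19 of 23 alternatives, adjusted p from 0.0119 to 0.13), and HPGDS, which is also on the mast cell list, fell by 3.13 on the log2 scale. The prostaglandin transporter SLCO2A1 rose by 2.36 ± 0.41 (SE; limma adjusted p = 0.00583). The list passed in 18 of 26 alternatives (adjusted p from 0.00582 to 0.493) and was lost without SP replicate 1 and without MP replicates 1 and 3 (camera adjusted p = 0.103, 0.0724 and 0.152), without replicate number 1 (0.142), at a mean of at least 5 FPKM (0.174), with array weights (0.0763) and after a correction for genomic span (0.0525). Without SP replicate 1 the median was −0.58. In fits without an MP library or a replicate number the filter also left out HPGDS. Fibroblast and mast cell markers fell in the same libraries (medians −3.20 and −3.58).

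Genes used to mark mesenchymal stem cells moved in both directions, 4 rising and 4 falling of 15, and 6 and 4 adjusted over the list alone (camera adjusted p = 0.603). ENG (endoglin), which endothelial cells also express, rose by 2.15 ± 0.44, while THY1, CD44 and PDGFRB had log2 fold changes of −4.56 ± 0.37, −2.51 ± 0.40 and −2.28 ± 0.39 (SE). Only 7 of 19 listed pluripotency and stemness genes were tested. POU5F1, SOX2, NANOG, LIN28A, SALL4, TERT, LGR5 and SOX9 were among those that missed the filter on low values. Of the 7 tested genes MYC rose by 1.84 ± 0.43 and the aldehyde dehydrogenases ALDH1A1 and ALDH1A3 had log2 fold changes of −3.62 ± 0.40 and −1.02 ± 0.27 (SE), with the same counts adjusted over the list alone. MYC was called in 19 of 23 alternatives (adjusted p from 0.00508 to 0.126) and ALDH1A3 in 12 of 16 (0.017 to 0.0798). The list did not pass (camera adjusted p = 0.918), and its median of 0.43 and its mean of −0.15 differ in sign.

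**Figure D3:**
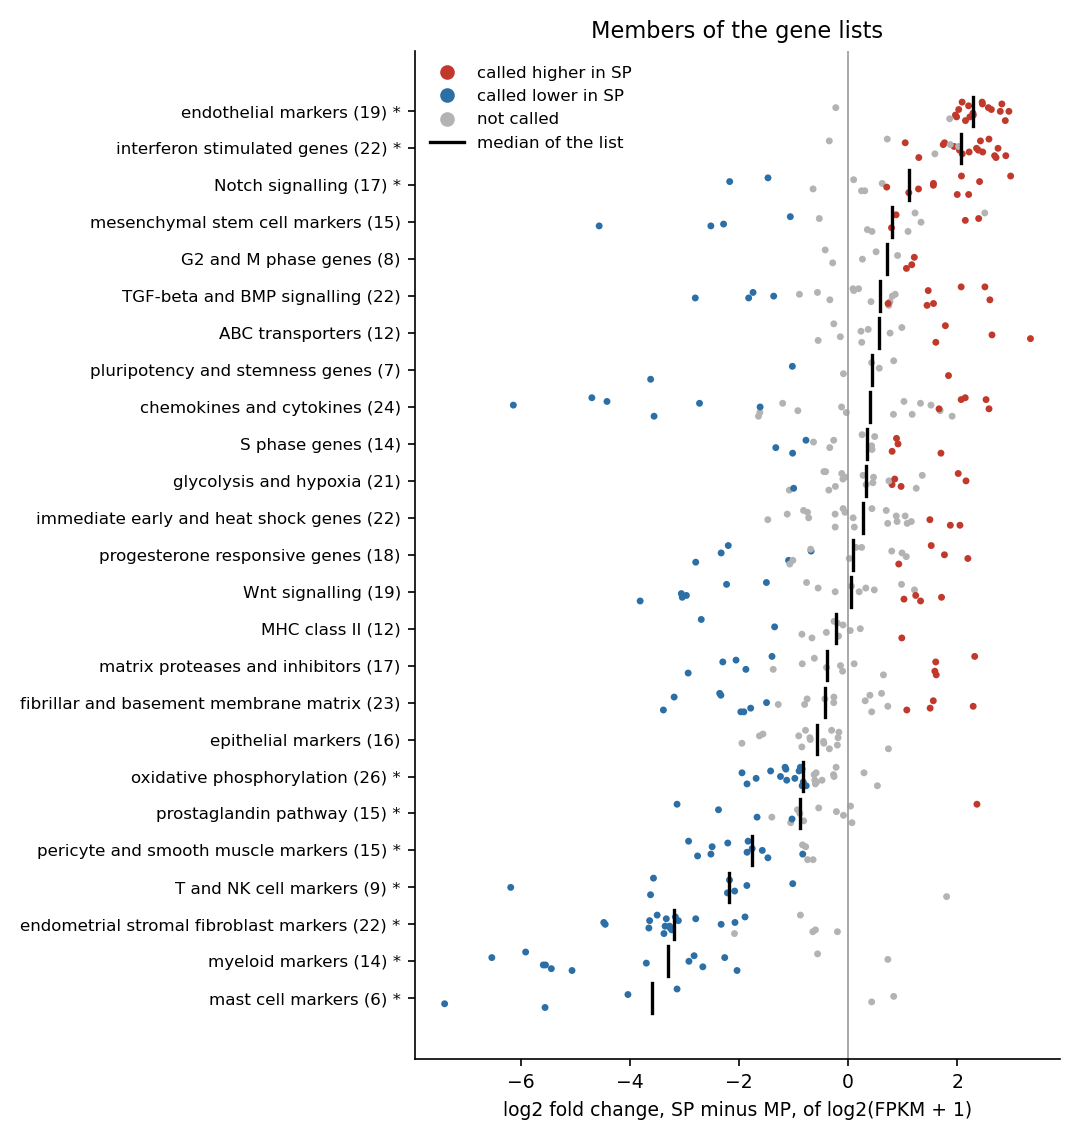
Log2 fold change, SP minus MP, of log2(FPKM + 1) on the x axis for the tested members of the 25 lists with at least 4 of them (y axis; tested members in brackets, an asterisk where camera with the preset correlation passed); each point is a gene, red if called higher and blue if called lower in SP, and a bar marks the median. Endothelial markers (median 2.29) and interferon stimulated genes (2.07) stand at the top, and myeloid (−3.31) and mast cell markers (−3.58) at the bottom.

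The other lists did not pass camera, and their called members went both ways except where stated. Of 18 progesterone responsive genes 4 rose and 5 fell, and 5 and 5 adjusted over the list alone (camera adjusted p = 0.87; median 0.08 and mean −0.12 differ in sign). The progesterone receptor gene PGR was at 1.52 ± 0.848 FPKM in SP and 12.3 ± 6.56 FPKM in MP (SD, n = 3 each; limma adjusted p = 0.00842), HAND2 and FGF10, the latter listed at 0 in SP replicate 1, had log2 fold changes of −2.79 and −2.19, and FOXO1 rose by 1.77. PGR and HAND2 are also on the stromal fibroblast list, whose median was −3.20. Of 19 Wnt genes 4 rose and 6 fell, and 6 and 6 adjusted over the list alone (camera adjusted p = 0.603; median 0.06 and mean −0.50 differ in sign), among them SFRP1, WNT2, DKK3 and SFRP2, with log2 fold changes of −3.05, −3.04, −2.96 and −3.81. Of 22 TGF-beta and BMP genes 7 rose and 4 fell, and 10 and 4 adjusted over the list alone (camera adjusted p = 0.358), with the inhibitory SMAD6 and SMAD7 rising by 2.60 and 2.51 and TGFBR3 and TGFB3 at −1.82 and −1.36. Of 24 chemokines and cytokines 5 rose and 6 fell, and 6 and 6 adjusted over the list alone (camera adjusted p = 0.66; median 0.40 and mean −0.34 differ in sign). With fry this list passed, downward (adjusted p = 0.0411), the only one of 26 alternatives in which it did, over a range of adjusted p from 0.0411 to 0.996. Besides CCL4, the log2 fold changes of CCL3, IL1B and TNF were −4.70, −4.42 and −2.72, and TNF is listed at 0 in SP replicate 2.

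Of 23 fibrillar and basement membrane matrix genes 4 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.358), and without MP replicate 2 alone the list passed, downward (0.0421; adjusted p from 0.0421 to 0.853 over 26 alternatives). HSPG2 (perlecan) rose by 2.29 ± 0.38 (SE), and COL6A1, COL6A2 and BGN had log2 fold changes of −3.38, −3.19 and −1.91. Of 17 matrix proteases and inhibitors 4 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.358), with MMP19, PLAUR, ADAMTS5 and TIMP1 at −2.93, −2.29, −1.87 and −1.39. Of 12 MHC class II genes CIITA rose by 0.99 and BOLA-DOA and BOLA-DOB fell (−2.69 and −1.34), and 2 fell adjusted over the list alone (camera adjusted p = 0.438). CIITA was called in only 6 of 21 alternatives (limma adjusted p from 0.00972 to 0.281) and was lost with pseudocounts of 0.1 and 0.5 (0.0626 and 0.0506), with no filter on low values (0.0972) and with median-of-ratios scaling (0.052). These genes have similar copies and vary between animals. Of 21 genes of glycolysis and hypoxia 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.358), SLC2A3, HK1 and PKM rising by 2.16, 2.02 and 0.97 and TPI1 falling from 264 to 132 FPKM; HK1 and PKM were each called in 16 of 23 alternatives (adjusted p from 0.00439 to 0.136 and from 0.00582 to 0.215) and TPI1 in 18 (0.00943 to 0.109). Of 14 S phase genes 4 rose and 3 fell, and 4 and 4 adjusted over the list alone (camera adjusted p = 0.644), with CCNE2, MCM7 and MCM5 rising by 1.70, 0.89 and 0.92 and RRM1 at −1.02. MCM5 and RRM1 were each called in 17 of 23 alternatives (adjusted p from 0.00924 to 0.135 and from 0.0152 to 0.136) and MCM7 in 19 (0.00651 to 0.124). Of 8 G2 and M phase genes PLK1, NUSAP1 and AURKA rose by 1.17, 1.22 and 1.07, also adjusted over the list alone, and none fell (camera adjusted p = 0.233). With no filter on low values this list passed (0.00661), the only one of 25 alternatives in which it did, over a range of adjusted p from 0.00661 to 0.635. NUSAP1 was called in 15 of 21 alternatives (adjusted p from 0.00765 to 0.123) and AURKA in 13 of 22 (0.009 to 0.233). Of 22 immediate early and heat shock genes NR4A2 and FOSL1 rose by 2.05 and 1.88 and ZFP36 from 633 to 1919.5 FPKM, none fell, and 1 rose adjusted over the list alone (camera adjusted p = 0.489). FOSL1 and ZFP36 were each called in 14 of 23 alternatives (adjusted p from 0.0155 to 0.247 and from 0.0135 to 0.203).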

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

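The tests of the splits, of the mitochondrial loci and of the cell type lists were chosen after their results were seen, whereas those of the span correction and of the mixing share were written down before.

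The row without a gene name, which no comparison used, pools immunoglobulin and uncharacterised genes and was higher in MP. Its mean was 12190 ± 6180 FPKM in MP and 1863 ± 346 FPKM in SP (SD, n = 3 each), with all MP values above all SP values (exact two-sided permutation test p = 0.1, the smallest it allows). No explanation was tested.

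The real split of the 6 libraries gave 4759 called genes and the highest of the other splits gave 2. Only 1 of the 10 splits gave as many as the real one, and with 10 splits the share cannot go under 0.1, too few to exclude chance.

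COX1, COX3, ATP6 and ATP8 are listed at 0 in the 3 MP libraries. A lack of mitochondrial transcripts in MP is argued against by the 9 other mitochondrially encoded genes, whose median log2 difference, MP minus SP, was 1.29, and above 0 in each MP library (0.59 in MP replicate 1, the lowest). A limit on fragments per locus in the authors' quantification stays open. From the ratios in SP, the 2 loci were expected to hold 766038 to 2248485 fragments in MP, and in 5 of 6 cases this exceeded the most fragments at a mitochondrial locus with a value, 866557. RN18S1, another very abundant gene, is listed at 0 in MP replicate 3 and stood at 14626 and 12901 FPKM in the other MP libraries and at 3644, 3115 and 4668 FPKM in SP replicates 1 to 3.

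Respiratory chain genes were lower in SP while fold changes rose along genomic span, from a median of −0.41 in the 1213 genes of shortest span to 0.25 in the 1213 of longest span. A difference between libraries along the listed locus span as the whole cause is argued against. After a correction of each library for this span the list still passed (camera adjusted p = 8.8e-05), with a median of −0.67, against −0.83 before. The listed span is not transcript length: that of NDUFA1, 45233 bp, overlaps NKAP and RNF113A. The correction thus cannot decide on an effect of transcript length. The median of ribosomal protein genes was −0.50 before and −0.16 after, so the trend could account for part of it. A biological difference between the populations, a different mix of cell types, and RNA quality or handling differing between the sorts, stay open and untested.

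Endothelial markers were high in SP and intermediate in MP replicate 3. A lower share of fibroblasts that raised every other cell type alike is argued against by the pericyte and smooth muscle markers. Their median was −1.76, and all 15 tested members lay under 0. Among them ACTA2, DES, CNN1 and LMOD1 were above 1 FPKM in every library, so the filter did not fix their direction. The myeloid list, on which this test was set, had a median of −3.31. The filter fixed the direction of myeloid members such as AIF1, so that median alone cannot decide. A larger share of endothelial cells in the SP gate is a candidate explanation, which needs the other cell types to be lower, as in the fibroblast median of −3.20 and the falls of mural and leukocyte markers but not in the epithelial list, which did not pass (median −0.57, camera adjusted p = 0.265), and no antibody gate that would remove such cells is given; EMCN, PLVAP and KDR, the most abundant markers, averaged 469, 436 and 255 FPKM in SP, and NOTCH4 and ENG of other lists are also expressed by endothelium. Whether stromal cells with endothelial transcripts would give the same values was not tested. More cells of the SP type in MP replicate 3 cannot be told apart from other causes. The median mixing share (quartiles in brackets) was 39.5% from endothelial markers (34.8 to 43.1), 25.1% from other genes higher in SP (9.22 to 44.9) and 40.4% from genes lower in SP (11.5 to 62.8). It was 65.1% from 14 fibroblast markers (60.1 to 70.3) and −2.05% from 7 myeloid markers (−90.5 to 29). From interferon stimulated genes it was 8.34% (4.86 to 19.1), and 27.1% against SP replicate 3 alone (12.6 to 46).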

How the results depend on the processing

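The span correction, the fit without genes listed at 0 and the matching by exact symbol were chosen after seeing the data. Under scalings, filters, pseudocounts and variance models the called genes stayed within 1.5 times of 4759 (3332 to 5040). Without 1 library or 1 replicate number, which leaves fewer samples, they ranged from 351 to 4455, those higher in SP from 105 to 2574, those lower from 246 to 1881, the lists passing from 6 to 11, and the variance on the first component from 69.7% to 78.8%, against 67.4% with no filter. With an estimated correlation 0 lists passed, and by exact symbol 9. ABCG2 missed the threshold with no filter (log2 fold change 1.61, limma adjusted p = 0.0948), without mitochondrial and ribosomal protein genes (1.46, 0.0787) and after the span correction (1.40, 0.0673), and ranged from 0.94 to 2.47 without libraries; the cause was not tested. Of 107 named genes that passed, 45 passed in every alternative with a value, and none changed direction. Except for ABCG2 and ABCB1, these genes were named for their calls in the same data. The filter also fixed the direction of some, so a kept direction is no independent support. Genes near the filter had a value in fewer alternatives, such as 15 for CD8B and TNF, against 23 for ABCB1.

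Signs turned only for results that did not pass. EPCAM was 0.0270 under total scaling and 0.0213 after the span correction, and −1.11 to 0.87 without libraries. HBQ1 was 0.13 after the span correction. The Wnt median was −0.23 with no filter, −0.0148 at a mean of 5 FPKM, −0.0701 without mitochondrial and ribosomal protein genes and −0.15 after the span correction. That of progesterone responsive genes was −0.12 and −0.0109 in the latter pair. Without libraries these medians ranged from −0.10 to 0.28 and from −0.15 to 0.45, immediate early genes from −0.0035 to 0.61, matrix genes from −0.76 to 0.17 and MHC class II from −0.63 to 0.15. A list's sign was taken from its median after the direction of camera had been seen. Camera's own direction turned, never with a call, for the pluripotency list in 11 of 23 alternatives, the progesterone list in 9, chemokines and S phase genes in 3 each and epithelial, immediate early and Wnt genes in 1 each, and for none of the 10 lists that passed.

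The replicate numbers were not shown to pair the samples. Deviations of same-numbered libraries correlated at 0.105, 0.533 and −0.0854, and 2 of the 6 libraries correlated best with their own number. Hints of pairing were that, per the file headers, both populations share their stroma numbers, that the second component ordered the numbers alike in both, that 4 of 4 genes with 1 library far apart in both populations shared its number, and that BOLA-DQA2 and BOLA-DQA5 were near 0 in replicate 2 of both. With the replicate block 4793 genes were called, 2435 higher and 2358 lower, 10 lists passed, and ABCG2 had a limma adjusted p of 0.0679 at the same fold change of 1.61.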

Other observations

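The genes in this part were chosen after their values were seen. SELP (P-selectin) was at 4244 ± 580.1 FPKM in SP and 1198 ± 1408 FPKM in MP, SELE (E-selectin) at 192 ± 22.8 and 48.0 ± 57.9 FPKM, and NOS3, the endothelial nitric oxide synthase, at 28.3 ± 1.88 and 6.74 ± 5.33 FPKM (SD, n = 3 each; limma adjusted p = 0.0375, 0.0308 and 0.0107). EFNB2, the ephrin B2 gene, was at 109 ± 40.9 FPKM in SP and 27.8 ± 17.5 FPKM in MP, and TM4SF1 at 5584 ± 1801 and 1518 ± 997 FPKM (SD, n = 3 each; limma adjusted p = 0.0115 and 0.0217). ACKR1, a chemokine receptor of venules, and THBD (thrombomodulin) did not pass, at 859 ± 145 and 228 ± 70.7 FPKM in SP and 384 ± 493 and 90.4 ± 69.4 FPKM in MP (SD, n = 3 each; limma adjusted p = 0.0874 and 0.0658). SELP stood at 210, 573 and 2811 FPKM in MP replicates 1 to 3. CCL21, a chemokine of lymphatic endothelium, was at most 0.138 FPKM in SP and 0.929 FPKM in MP.

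Genes around the aryl hydrocarbon receptor did not all move with CYP1A1. The receptor gene AHR and its target TIPARP rose by 2.24 ± 0.61 and 2.07 ± 0.48 on the log2 scale (SE; limma adjusted p = 0.0238 and 0.0144), while CYP1B1 was at 2.69 ± 1.39 FPKM in SP and 7.38 ± 4.02 FPKM in MP (SD, n = 3 each; limma adjusted p = 0.0616). TNFAIP3 and NFKB1 of the NF-kappaB pathway rose by 2.74 ± 0.57 and 1.51 ± 0.51, and the interferon receptor gene IFNAR1 by 1.61 ± 0.51 (SE; limma adjusted p = 0.00989, 0.0487 and 0.0392).

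The MHC class II gene BOLA-DQA2 was at 13.0, 0.126 and 8.38 FPKM in SP replicates 1 to 3 and at 23.4, 0.526 and 21.9 FPKM in MP replicates 1 to 3, BOLA-DQA5 at 3.36, 0 and 3.76 FPKM and at 4.78, 0.0581 and 4.78 FPKM, and BOLA-DQB at 7.82, 0 and 2.75 FPKM and at 3.82, 0.0207 and 3.21 FPKM. These genes vary between animals. In replicate 2 of both populations they were at most 0.526 FPKM, against at least 2.75 FPKM in replicates 1 and 3. These values argue against a single animal behind all 3 replicates. They do not tell replicates 1 and 3 apart, and no genotype was tested.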
